A study of Mus musculus with 17 samples.

How the data were processed

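RNA of CD8 T cells from OT-I mice, isolated or sorted by flow cytometry per the series description, was measured on Illumina mouse bead arrays with biotin-labelled cRNA, per the labels, in 17 samples. These were 5 naive, 3 memory, 4 LSEC-primed and 5 effector samples, grouped as labelled, although 1 LSEC-primed sample carries a cell type label that differs from the 3 others and effector sample 8 gives spleen as its source. The series title counts 20 samples, and 3 further columns without labels were not analysed here. The authors deposited a table of non-normalised signal, and per the file headers its values are intensity per probe on a linear scale, with no normalisation between arrays. A second deposited table holds intensity values that, read from the values themselves, were quantile normalised by the authors on the linear scale. Image analysis software and scanner settings are not given in the sources used here.

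The non-normalised table was background corrected with the normexp model (offset 50), quantile normalised and set on the log2 scale in limma 3.58.1 under R 4.3.3. It has no detection p-values or control probes, so the planned detection filter was replaced by its planned fallback, the array median. Of 45281 probes, 35237 lay above the array median of all probes on at least 3 arrays and were kept. The platform annotation, of 2016, gives 1 gene symbol for 34885 probes, several for 18 and none for 10378. The probe with the highest mean stood for each gene symbol, leaving 23699 features, of which 16462 were named genes and 7237 had no symbol. For lower bounds on fold changes, a background level was set on each array as the mode plus 3 SD of the lower side of its intensities, a definition chosen after seeing the data. A fold against a group with no array above that level is given as "at least".

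All groups were fitted in 1 linear model with a mean per group and empirical Bayes moderation (limma, residual df 13, prior df 3.16). P-values were adjusted by Benjamini-Hochberg over all features and called under 0.05, and the count with a change of at least 2-fold stands beside. No covariate was used, since the labels name no batch. No paired analysis was possible because no sample number occurs in more than 1 group. The 3 main comparisons set LSEC-primed cells against naive, effector and memory cells, and 3 reference comparisons set effector and memory cells against naive cells and memory against effector cells. Comparisons, tests, gene lists and the rule for naming genes were fixed before the data were examined.

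The 31 gene lists, 11 of them markers of other cells or of sex, named 649 members, of which 581 were measured. In the glycolysis list, matching by synonym took Pigq, which is not a glycolysis gene, for Gpi1, and the enolase copy Eno1b for Eno1. Pigq was not called in any comparison. Lists were tested with camera at its preset inter-gene correlation of 0.01 and again with an estimated correlation, adjusted over the lists, and member counts are also given adjusted over the list alone. The genes named are the 8 highest and 8 lowest of each main comparison and the 3 highest and 3 lowest of each reference comparison, among called genes with groups that do not overlap. To these were added the 6 with the largest smallest difference in each direction among genes particular to LSEC-primed cells, up to 4 called members of each list, and 27 landmark genes, of which 24 had a probe. From the list members and the landmarks, the examples named were chosen after their values were seen. Fold changes sharing the naive arrays were compared with 100 simulations of unchanged groups and with 10 splits of the naive arrays between the comparisons.

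The steps were tested on simulated data with 200 changed features of 23699. At 1.5-fold, 2-fold and 4-fold, 67.6%, 90.9% and 99.2% were recovered for LSEC-primed over naive, 67.8%, 89.8% and 99.2% over effector, and 57.8%, 85.8% and 98.6% over memory cells. False calls made up 5.03%, 4.25% and 5.62%. Every simulated array had the same spread per gene. In the data memory sample 5 had a limma array weight, lower for noisier arrays, of 0.2207, against at least 0.6536 on the others. The rates over memory cells may therefore not carry over to these arrays. A list of 25 genes shifted by 0.5 was called in 10 of 10 simulations, and 2 of 290 unshifted lists were called. The simulated genes varied independently and the lists were drawn at random. Members of real lists moved together, with estimated correlations such as 0.122 for the cell cycle and 0.562 for macrophage markers. The rate for unshifted lists therefore does not carry over to the real lists.

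The alternatives were the authors' processed values, no background correction, median scaling, cyclic loess, no filter, a stricter filter, the mean of all probes or every probe by itself, eBayes with trend and robust, array weights, an estimated inter-gene correlation, only the 2 groups compared, a test beyond 1.5-fold (limma treat), and each array left out in turn. Another 5 were chosen after seeing the data: a filter on the estimated background, leaving out both dim memory arrays, and the first component of the residuals, sex read from Xist and Eif2s3y, or the sample number as a covariate.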

Results

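Gene expression was measured on Illumina mouse bead arrays in CD8 T cells of OT-I mice, whose transgenic T cell receptor recognises an ovalbumin peptide. The 17 samples formed 4 groups. There were 5 samples of naive cells from spleen, 4 of cells primed in coculture with liver sinusoidal endothelial cells (LSEC), 5 of effector cells activated by dendritic cells, and 3 of memory cells taken from spleen 3 months after infection with Listeria carrying ovalbumin. On 3 of the 4 LSEC-primed samples the submitters also used the name Tpm, which the series title gives as partial memory T cells, and the title sets these cells beside naive, effector and memory cells. The labels name a dendritic cell coculture for 4 of the effector samples and spleen for effector sample 8. No label says whether the samples of a group came from separate animals or cultures, so the p-values measure only the spread between these samples. Naive sample 13, LSEC-primed sample 14 and effector sample 17 carried Y-linked signal and the other samples did not, so the samples of these 3 groups came from more than 1 animal. Memory samples 3 and 5 were the dimmest arrays, with a mean intensity of 140 and 96.7 against at least 227 on the others. On memory sample 5, 15.4% of probes lay above the estimated background, against 25.9% to 32.7% on the other arrays. The number of arrays limits the precision.

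The 4 groups separated on the first 3 principal components, which held 42.82%, 16.68% and 11.85% of the variance. Effector samples lay at 53.5 ± 4.81 on component 1 (SD, n = 5), LSEC-primed samples at 1.31 ± 8.57 (n = 4), naive samples at -34.4 ± 1.39 (n = 5) and memory samples at -33.6 ± 5.22 (n = 3). Memory samples stood apart on component 2 and LSEC-primed samples on component 3, where they averaged 32.6 ± 13.35. Within groups, the correlation of arrays across all 45281 probes ran from 0.9364 in the memory group to 0.9894 in the effector group, and no pair of arrays held the same values.

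**Figure D1:**
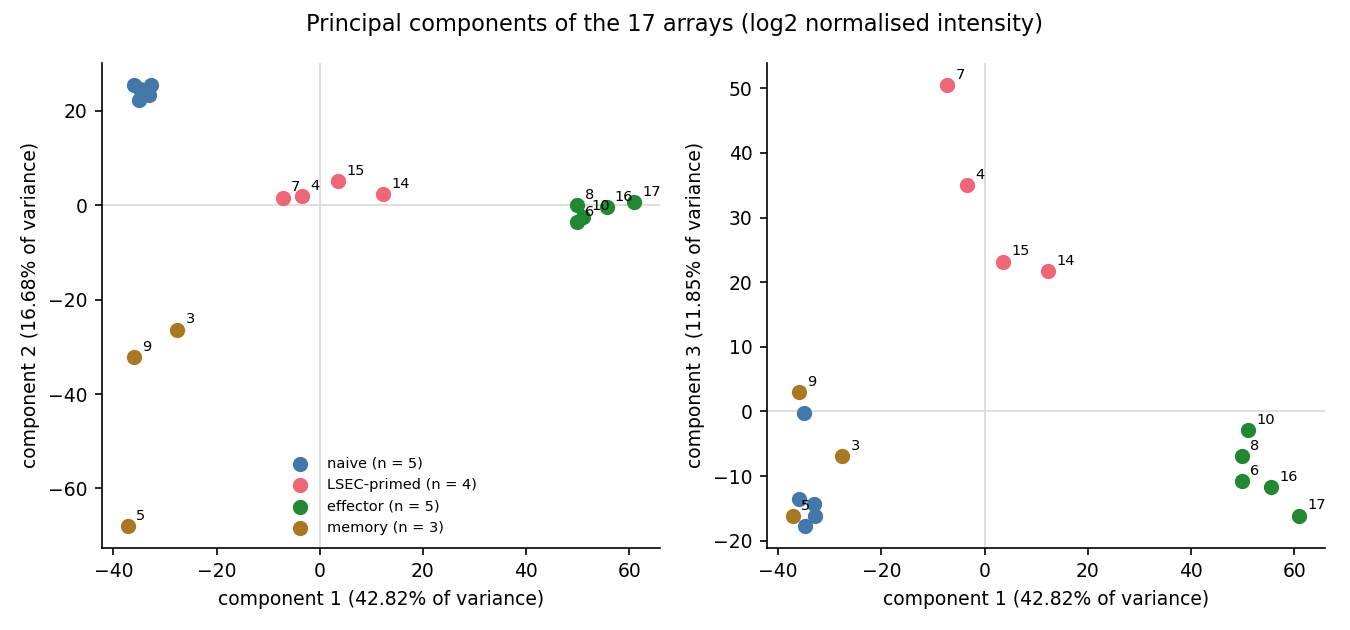
Scores of the 17 arrays on principal component 1 (x axis) against component 2 (left) and component 3 (right) of log2 normalised intensity, coloured by group, with sample numbers beside all points but the naive ones. LSEC-primed samples lie between -7.20 and 12.3 on component 1, between the naive and effector samples, and between 21.7 and 50.5 on component 3, above all other samples.

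The first comparison set LSEC-primed cells against naive cells, the state before priming. Genes of quiescence were lower in LSEC-primed cells, and a lymphocyte chemokine and an inhibitory receptor were among the genes that rose most. The lymphocyte chemokine Xcl1 rose by 4.78 on the log2 scale (SE 0.30, adjusted p = 2.65e-08 by limma with Benjamini-Hochberg adjustment, n = 4 and 5), and the inhibitory receptor Lag3, above background on 2 of the 5 naive arrays, rose by 4.15 (SE 0.50, adjusted p = 1.98e-05). Kit, a receptor tyrosine kinase above background on 2 of the naive arrays, rose by 4.14 (SE 0.45). The interferon-gamma-induced chemokine Cxcl9, above background on 1 of them, rose by 3.74 (SE 0.33). Synpo, an actin-binding protein, rose by 3.58 (SE 0.24, 2 naive arrays above background). The quiescence factor Klf2 fell by 2.77 (SE 0.34, adjusted p = 2.42e-05), from 13.16 ± 0.09 to 10.38 ± 0.88 (SD), and the chemokine Ccl5 fell by 1.91 (SE 0.22). Among the strongest losses were the AP-1 subunit Fosl2, which fell by 3.58 (SE 0.16), the MAP kinase phosphatase Dusp10, which fell by 3.43 (SE 0.11), and the AMP deaminase Ampd1, which fell by 3.27 (SE 0.13, 1 LSEC-primed array above background).

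At an adjusted p under 0.05, 2601 of 16462 genes were called between LSEC-primed and naive cells, 1653 higher and 948 lower, and 684 of them changed at least 2-fold. The values of the 2 groups did not overlap for 2565 genes, 15.6% of those tested, where chance gives 1.59%. After scaling each array to a common median in place of quantile normalisation, 861 genes were called.

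Among 17 measured genes of quiescence and lymph node homing, 11 fell, 1 rose and 5 were not called, and 11 fell and 1 rose when adjusted over the list alone. The camera test placed the list below other genes (adjusted p = 3.7e-10, and adjusted p = 0.00136 with an estimated correlation). Klf3, a Krüppel-like factor, fell by 2.13 (SE 0.12), the interleukin 6 receptor Il6ra fell by 2.01 (SE 0.17) and the growth factor binding protein Igfbp4 fell by 2.23 (SE 0.18). Klf3 was above background on 2 and Il6ra on 1 of the 4 LSEC-primed arrays. Id3 was the member that rose, by 1.06 (SE 0.18). Of 27 measured genes of oxidative phosphorylation, 9 rose and none fell, with 10 rising when adjusted over the list alone (camera adjusted p = 5.14e-05, and adjusted p = 0.0102 with an estimated correlation). The members that rose did so by less than 2-fold, among them the succinate dehydrogenase subunit Sdhb (0.75, SE 0.11) and the cytochrome oxidase subunit Cox5a (0.70, SE 0.09), and the calls of these 2 genes ended with median scaling.

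The lists that follow were called by camera only with its preset correlation. Of 47 measured genes of the cell cycle and DNA replication, 21 rose and 1 fell, or 25 and 1 adjusted over the list alone, led by the spindle gene Nusap1 (1.63, SE 0.31) and the mitotic kinase Plk1 (1.63, SE 0.29). For that list camera gave adjusted p = 4.2e-09 and adjusted p = 0.0718 with an estimated correlation. In the glycolysis list 8 of 20 rose, 9 adjusted over the list alone, among them the triosephosphate isomerase gene Tpi1 (2.33, SE 0.24), with adjusted p = 0.000262 and adjusted p = 0.313 with an estimated correlation. Of 24 inhibitory receptors and tolerance regulators, 8 rose and 3 fell, or 10 and 4 adjusted over the list alone, and beside Lag3 the transcription factor Egr3 (2.41, SE 0.29), Cd160 (2.08, SE 0.17) and the immunoglobulin-like ligand Cd200, above background on 2 of the naive arrays (2.19, SE 0.20), rose. That list had adjusted p = 0.0385 and adjusted p = 0.368 with an estimated correlation. Of 22 immediate-early and heat shock genes, which respond within minutes to stimulation or handling, 10 fell and 3 rose, or 12 and 3 adjusted over the list alone. Ppp1r15a fell by 3.74 (SE 0.45), Junb by 3.27 (SE 0.45) and Fos fell by 2.67 (SE 0.62), with adjusted p = 0.000372 for the list and adjusted p = 0.368 with an estimated correlation. Of 20 fatty acid oxidation genes 6 rose, or 9 with 1 falling adjusted over the list alone, with adjusted p = 0.0385 and adjusted p = 0.368 with an estimated correlation. The inhibitory receptor call ended without naive sample 2 or 13 or LSEC-primed sample 15, at list medians of 0.05, 0.07 and 0.09. The fatty acid oxidation call ended without naive sample 2 or LSEC-primed sample 4, 14 or 15, at list medians of 0.18, 0.21, 0.13 and 0.17, and also with median scaling.

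Transcripts listed as markers of endothelial and stromal cells were present on the same LSEC-primed arrays as the changes above. Of 22 measured markers of liver sinusoidal endothelium, 11 rose and none fell, or 12 and 1 adjusted over the list alone (camera adjusted p = 3.7e-10, and adjusted p = 0.0189 with an estimated correlation). Of 12 markers of stellate cells and fibroblasts, 5 rose, or 7 adjusted over the list alone (adjusted p = 3.22e-05, and adjusted p = 0.0488 with an estimated correlation). Genes at background on every naive array were at least 31.9-fold higher for the secreted binding protein Igfbp7 (adjusted p = 1.12e-06), 12.0-fold for the vascular growth factor Angpt2, 7.38-fold for the matrix proteoglycan Bgn, 5.85-fold for Egfl7 and 4.43-fold for the endothelial receptor Robo4. The ubiquitin-like gene Ubd, induced by interferon-gamma in many cell types, was at least 9.44-fold higher. Of the 22 endothelial markers, 4 lay above background on all 5 naive arrays. In the opposite direction, 3 of 8 erythroid markers fell (adjusted p = 0.000221, and adjusted p = 0.166 with an estimated correlation), 3 adjusted over the list alone, and the haemoglobin gene Hba-a1 was at least 33.7-fold lower in LSEC-primed cells (adjusted p = 1.47e-07). The haemoglobin gene Hbb-bt was at least 45.3-fold lower, and Hbb-bs, above background on 1 LSEC-primed array, fell by 5.98 (SE 0.34).

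The remaining lists were not called between LSEC-primed and naive cells. Of 19 memory-associated surface molecules 6 rose and 3 fell, or 7 and 4 adjusted over the list alone (camera adjusted p = 0.441), with gains of the chemokine receptor Cxcr3 (2.39, SE 0.20) and the activating receptor Klrk1, above background on 2 of the naive arrays (2.77, SE 0.17). Of 16 cytotoxic effector molecules 4 rose and 1 fell (adjusted p = 0.332), and of 23 secreted cytokines and chemokines 3 rose and 2 fell (adjusted p = 0.386). Of 16 effector and memory transcription factors 4 rose, with Irf8 up by 2.31 (SE 0.28, 4 naive arrays above background), and 2 fell (adjusted p = 0.359). Adjusted over the list alone, the counts of these 3 lists were the same. Adjusted p was 0.206 for cytokine receptors and their SOCS feedback, 0.0801 for cholesterol biosynthesis, 0.128 for interferon-stimulated genes, 0.373 for trafficking and adhesion, 0.378 for apoptosis regulators, 0.59 for costimulatory receptors, 0.699 for the T cell receptor complex, 0.939 for MYC targets and 0.999 for the unfolded protein response. Among markers of other cells it was 0.116 for neutrophils, 0.216 for CD4 T cells, 0.356 for dendritic cells, 0.373 for B cells and for NK cells, 0.699 for sex-linked genes, 0.968 for macrophages and 0.999 for hepatocytes.

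**Figure D2:**
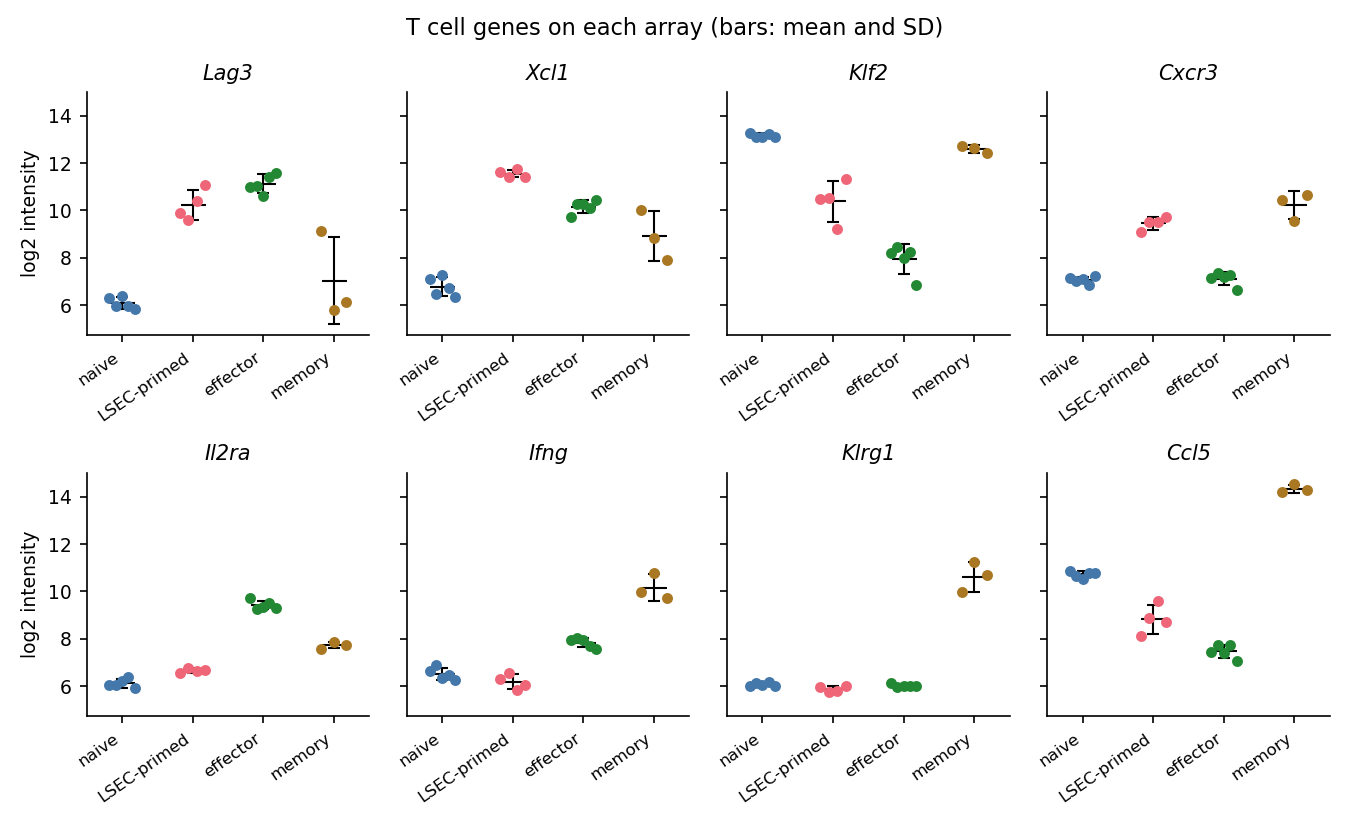
Log2 normalised intensity (y axis) of 8 T cell genes on each array, by group (x axis); points are arrays and bars are the mean and SD. Lag3 and Xcl1 are high in LSEC-primed and effector cells, Klf2 in LSEC-primed cells lies between its levels in naive and effector cells, and Ifng, Klrg1 and Ccl5 are highest in memory cells.

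The comparison with effector cells asks how priming by LSEC differs from activation by dendritic cells. LSEC-primed cells carried far lower levels of genes for growth metabolism and division than effector cells. The metallothionein gene Mt1 was lower by a log2 difference of -4.42 (SE 0.51, adjusted p = 9.69e-06 by limma, n = 4 and 5), the fatty acid desaturase Scd1 by -4.40 (SE 0.24), the costimulatory receptor Tnfrsf4 by -4.09 (SE 0.27) and the mitochondrial gene Mgarp by -4.54 (SE 0.29). The interleukin 2 receptor alpha chain Il2ra (-2.76, SE 0.11), perforin, encoded by Prf1 (-2.11, SE 0.38), the death receptor ligand Fasl (-1.89, SE 0.19), and interferon gamma, encoded by Ifng (-1.66, SE 0.20), were also lower, and Ifng was above background on 1 of the 4 LSEC-primed arrays. In the other direction, the integrin gene Itgae, which encodes CD103, was higher by 3.74 (SE 0.50, adjusted p = 4.22e-05), Cxcr3 by 2.34 (SE 0.20), Klf2 by 2.44 (SE 0.34), the interferon-inducible gene Ifi213 by 4.40 (SE 0.16) and the channel gene Calhm6 by 3.54 (SE 0.16). The thyroglobulin gene Tg (-3.87, SE 0.17) and the transcription factor Bhlhe40 (-3.78, SE 0.39) were among the lowest. Scd1 was above background on 3 of the 4 LSEC-primed arrays and Ifi213 on 4 of the 5 effector arrays.

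Between LSEC-primed and effector cells 2921 genes were called, 1565 higher and 1356 lower, with 889 changed at least 2-fold. The share of higher calls was 53.6%, and with median scaling 1276 genes were called, of which 31.2% were higher. Values did not overlap for 3020 genes (18.3%), where chance gives 1.59%.

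Of 47 measured cell cycle genes 39 fell and none rose relative to effector cells, or 40 adjusted over the list alone (camera adjusted p = 5.87e-30, and adjusted p = 0.00163 with an estimated correlation), with the mitotic kinase Aurkb at -2.55 (SE 0.33) and the topoisomerase Top2a at -2.48 (SE 0.41). In the glycolysis list 17 of 20 fell, 17 adjusted over the list alone (adjusted p = 1.62e-20, and adjusted p = 0.00447 with an estimated correlation), among them the aldolases Aldoc (-3.98, SE 0.20) and Aldoa (-2.65, SE 0.32). In cholesterol biosynthesis 15 of 17 fell, 16 adjusted over the list alone (adjusted p = 3.34e-23, and adjusted p = 0.000344 with an estimated correlation), with the farnesyl diphosphate synthase Fdps at -3.61 (SE 0.24) and the sterol demethylase Cyp51 at -2.70 (SE 0.24). Of 27 oxidative phosphorylation genes 5 fell, 6 adjusted over the list alone (adjusted p = 0.00182, and adjusted p = 0.0207 with an estimated correlation). Of 21 genes of the T cell receptor complex 7 rose and 1 fell, or 8 and 1 adjusted over the list alone (adjusted p = 0.0018, and adjusted p = 0.015 with an estimated correlation). Median scaling ended the oxidative phosphorylation and T cell receptor calls, at list medians of -0.49 and 0.13.

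Interferon-stimulated genes were higher in LSEC-primed than in effector cells for 13 of 32 members and lower for none, or 16 and 1 adjusted over the list alone (camera adjusted p = 3.06e-07, and adjusted p = 0.185 with an estimated correlation). Ifit3, at background on every effector array, was at least 3.46-fold higher (adjusted p = 0.00495), and the guanylate binding protein Gbp2 was higher by 1.95 (SE 0.27). Of 15 costimulatory receptors and ligands 5 fell and 3 rose, or 8 and 4 adjusted over the list alone (adjusted p = 0.0193, and adjusted p = 0.227 with an estimated correlation), with Tnfrsf18 (-2.54, SE 0.36) and Tnfrsf9 (-1.91, SE 0.28) among those that fell. Of 24 inhibitory receptors and tolerance regulators 9 rose and 1 fell, the same as adjusted over the list alone (adjusted p = 0.0262, and adjusted p = 0.295 with an estimated correlation). Egr3 (2.03, SE 0.29) and Egr2 (1.53, SE 0.29) led them, while Lag3 differed by -0.89 (SE 0.50, adjusted p = 0.335). Of 21 unfolded protein response genes 5 fell and 2 rose, the same as adjusted over the list alone (adjusted p = 0.0291, and adjusted p = 0.165 with an estimated correlation). The asparagine synthetase Asns was among those that fell (-2.62, SE 0.22). MYC targets rose for 4 of 21 and fell for 1 (adjusted p = 0.0291, and adjusted p = 0.418 with an estimated correlation). Fatty acid oxidation genes fell for 5 of 20 (adjusted p = 0.0401, and adjusted p = 0.295 with an estimated correlation). Both counts were the same adjusted over the list alone. Left-out samples ended the unfolded protein response call (LSEC-primed sample 7, list median -0.06), the MYC call (LSEC-primed samples 4 and 15 and effector sample 8, medians 0.24, 0.30 and 0.30) and the fatty acid call (LSEC-primed samples 4, 7 and 15, memory sample 5, and effector samples 8, 16 and 17, medians -0.09, -0.04, -0.14, -0.10, -0.14, -0.09 and -0.12). Median scaling ended the inhibitory receptor, MYC and fatty acid calls, at list medians of 0.05, 0.16 and -0.28.

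Endothelial markers rose for 12 of 22 and fell for 1 relative to effector cells, or 13 and 1 adjusted over the list alone (camera adjusted p = 1.11e-08, and adjusted p = 0.0207 with an estimated correlation). Stellate cell markers rose for 5 of 12, or 7 with 1 falling adjusted over the list alone (adjusted p = 0.000274, and adjusted p = 0.0599 with an estimated correlation). Angpt2, at background on every effector array, was at least 12.4-fold higher in LSEC-primed cells, Cxcl9 at least 12.8-fold and Ubd at least 9.73-fold. Igfbp7 was higher by 3.41 (SE 0.47). Igfbp7 and Egfl7 lay above background on all 5 effector arrays, at 7.94 ± 0.19 and 8.25 ± 0.32. Of 18 macrophage markers, the lysozyme genes Lyz1 and Lyz2 rose, 2 adjusted over the list alone (camera adjusted p = 0.0029, and adjusted p = 0.522 with an estimated correlation). That list was no longer called without LSEC-primed sample 14, where its median was 0.12, and Lyz1 stood at 13.28 on that array against 8.44 to 8.49 on the other LSEC-primed arrays.

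**Figure D3:**
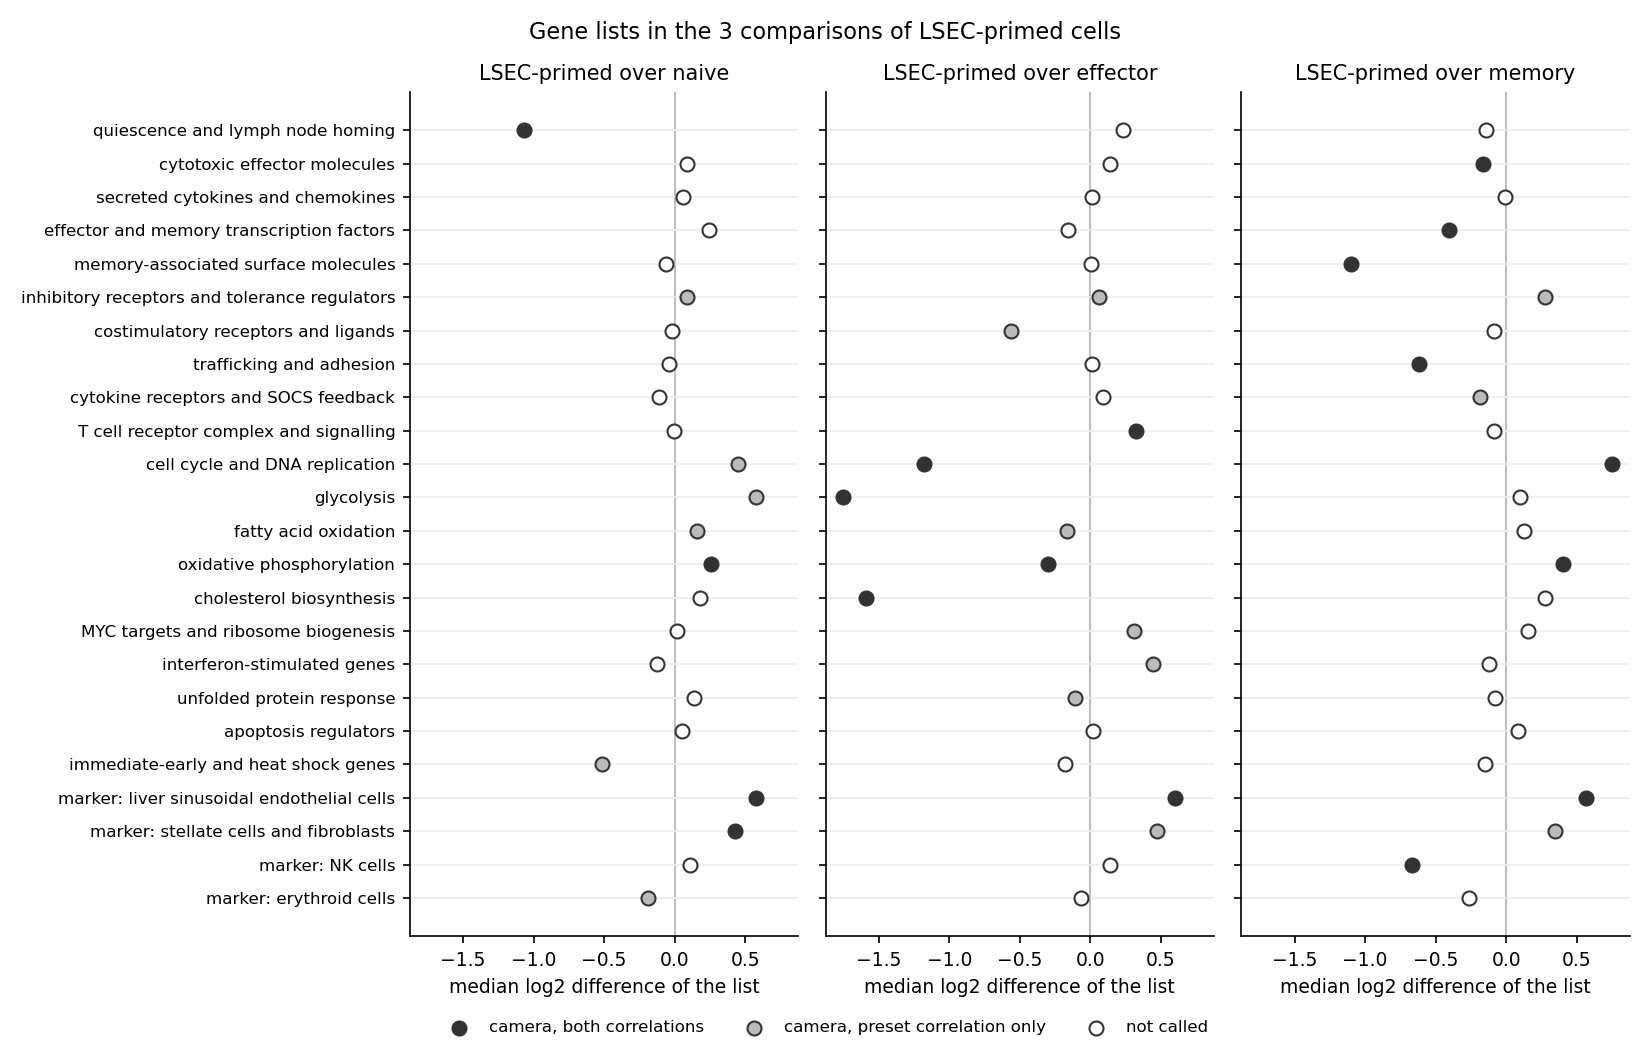
Median log2 difference (x axis) of 24 gene lists (y axis) in the 3 comparisons of LSEC-primed cells with naive, effector and memory cells. Dark points are lists called by camera with both correlations, grey points with the preset correlation only and open points were not called; the quiescence list sits at -1.07 against naive cells, glycolysis at -1.75 against effector cells and memory-associated surface molecules at -1.10 against memory cells.

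The comparison with memory cells, 3 samples of which 2 were dim, asks how the LSEC-primed state compares with memory after infection. Most of the listed surface molecules of memory cells, and some of their effector transcripts, were lower in LSEC-primed cells. The receptor Klrg1, the chemokine receptor Cx3cr1 and the sphingosine receptor S1pr5 lay at background on every LSEC-primed array and were at least 19.4-fold, 17.3-fold and 23.4-fold lower than in memory cells (adjusted p = 5.89e-11, 2.08e-12 and 1.26e-11 by limma, n = 4 and 3). Ccl5 was lower by a log2 difference of -5.51 (SE 0.25), Ifng by -3.98 (SE 0.23), the granzyme Gzmm by -3.76 (SE 0.12) and the repressor Zeb2 by -4.43 (SE 0.17). LSEC-primed cells held more Itgae (3.44, SE 0.57), Xcl1 (2.64, SE 0.34), Lag3 (3.22, SE 0.57), Egr3 (2.92, SE 0.33) and Hivep3, a zinc finger regulator (3.65, SE 0.45), together with the actin crosslinker Actn1 (3.48, SE 0.52), Kit (3.59, SE 0.52) and the tight junction gene Cldn10 (3.24, SE 0.34). Lag3, Kit and Cldn10 were above background on 1 of the 3 memory arrays, Hivep3 and Actn1 on 2, and Ifng and Gzmm on 1 of the 4 LSEC-primed arrays. The haemoglobin genes Hba-a1 and Hbb-bt were at least 24.2-fold and 36.8-fold lower, and Hbb-bs fell by 5.67 (SE 0.39), as against naive cells.

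A total of 2554 genes were called between LSEC-primed and memory cells, 1577 higher and 977 lower, and 788 changed at least 2-fold. The share of higher calls was 61.7%, but 97.4% with median scaling. Values did not overlap for 3119 genes (18.9%), where chance gives 5.71%. The count was 1221 with cyclic loess normalisation, 1144 with only the 2 groups compared, 1658 with array weights and 1383 without both dim memory arrays, the last chosen after seeing the data.

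Memory-associated surface molecules fell for 13 of 19 and rose for 2, or 14 and 2 adjusted over the list alone (camera adjusted p = 5.64e-14, and adjusted p = 4.53e-05 with an estimated correlation). The interleukin 18 receptor chains Il18r1 (-4.62, SE 0.39) and Il18rap (at least 8.7-fold lower) were among them. Of 16 transcription factors 7 fell and 4 rose, or 8 and 4 adjusted over the list alone (adjusted p = 0.00134, and adjusted p = 0.0269 with an estimated correlation). Of 16 cytotoxic molecules 5 fell and 1 rose, the same as adjusted over the list alone (adjusted p = 0.00803, and adjusted p = 0.0269 with an estimated correlation). The member that rose was the lysosomal gene Lamp2 (1.61, SE 0.14). Trafficking and adhesion genes fell for 11 of 22 and rose for 3, or 13 and 4 adjusted over the list alone (adjusted p = 0.00134, and adjusted p = 0.0269 with an estimated correlation). These 3 calls ended with median scaling, where the list medians were 0.47 for transcription factors, 0.24 for cytotoxic molecules and 0.04 for trafficking. With every probe a feature of its own, the cytotoxic and trafficking calls ended too, at list medians of -0.02 and -0.03. NK cell markers, some of which memory CD8 T cells also carry, fell for 5 of 10, 5 adjusted over the list alone (adjusted p = 3.52e-05, and adjusted p = 0.00934 with an estimated correlation), with the receptor Klre1 at -3.11 (SE 0.32).

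Cell cycle genes were higher in LSEC-primed than in memory cells for 22 of 47 and lower for 1, or 28 and 2 adjusted over the list alone (camera adjusted p = 1.63e-11, and adjusted p = 0.0269 with an estimated correlation), with Nusap1 at 2.53 (SE 0.36). Oxidative phosphorylation genes rose for 10 of 27, 11 adjusted over the list alone (adjusted p = 3.52e-05, and adjusted p = 0.00827 with an estimated correlation). Inhibitory receptors and tolerance regulators rose for 10 of 24 and fell for 1, or 11 and 2 adjusted over the list alone (adjusted p = 0.00134, and adjusted p = 0.105 with an estimated correlation), with Egr2, above background on 1 memory array, at 2.90 (SE 0.33) and Ctla4 at 2.80 (SE 0.59). Cytokine receptors fell for 6 of 23 and rose for 1, or 8 and 1 adjusted over the list alone (adjusted p = 0.0333, and adjusted p = 0.1 with an estimated correlation). Endothelial markers rose for 13 of 22 and fell for 1, or 14 and 2 adjusted over the list alone (adjusted p = 5.9e-08, and adjusted p = 0.0269 with an estimated correlation). Stellate cell markers rose for 5 of 12, or 5 with 1 falling adjusted over the list alone (adjusted p = 0.00249, and adjusted p = 0.1 with an estimated correlation). The endothelial marker that fell was Fcgr2b, an Fc receptor gene at 10.65 ± 0.42 on the memory arrays. B cell markers fell for 3 of 12, 4 adjusted over the list alone (adjusted p = 0.0319, and adjusted p = 0.11 with an estimated correlation). The cytokine receptor call ended without memory sample 3 or 9 or LSEC-primed sample 4, at list medians of -0.15, -0.27 and -0.11, and with median scaling, at 0.20. The B cell call ended without memory sample 3 or 5, at list medians of -0.20 and -0.15. Memory sample 3 carried several genes high on LSEC-primed arrays, such as Igfbp7 at 9.93 and Lag3 at 9.13, where memory sample 9 stood at 6.12 and 6.11. Lag3 was also high in effector cells, and Igfbp7 lay above background on every effector array.

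**Figure D4:**
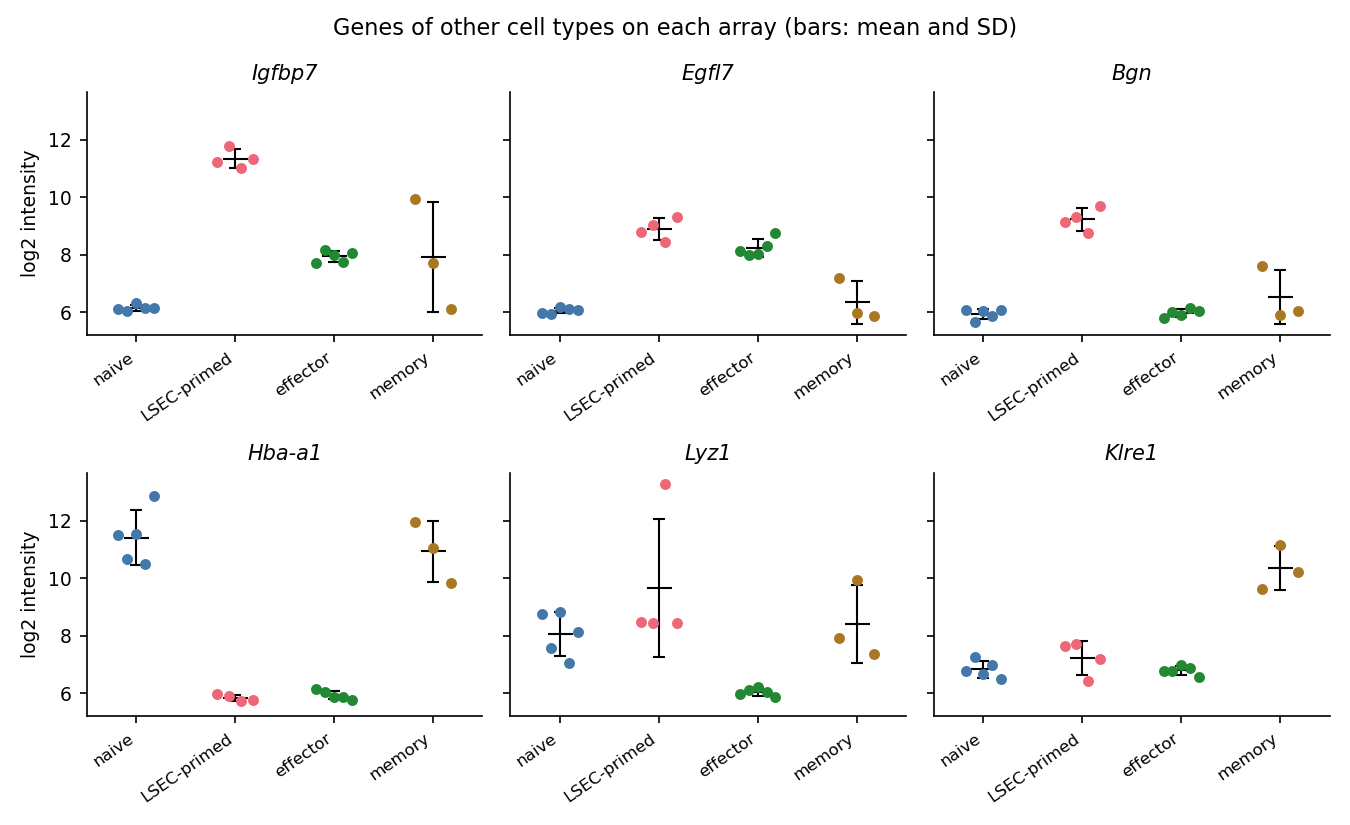
Log2 normalised intensity (y axis) of 6 genes chosen as markers of cells other than T cells on each array, by group (x axis); points are arrays and bars are the mean and SD. Igfbp7, Egfl7 and Bgn are highest on LSEC-primed arrays, Igfbp7 and Egfl7 are also above background on effector arrays, Hba-a1 is high in naive and memory cells, and Lyz1 reaches 13.28 on a single LSEC-primed array.

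Landmark genes of CD8 T cell states were read in every comparison. Ccr7, a lymph node homing receptor, averaged 10.36 in naive, 8.82 in LSEC-primed, 9.18 in effector and 6.87 in memory cells (above background on 2 of 3 arrays), and differed by -1.53 (SE 0.29, adjusted p = 0.0015) between LSEC-primed and naive cells. The interleukin 7 receptor Il7r was lower in LSEC-primed than in naive cells (-1.66, SE 0.25) and memory cells (-1.75, SE 0.28). The adhesion receptor Cd44 stood at 8.19 in LSEC-primed cells, between 7.20 in naive and 9.01 and 9.28 in effector and memory cells. These Il7r and Cd44 calls ended with median scaling, and that of Cd44 against effector cells (-0.81, SE 0.21) also without LSEC-primed sample 7 (-0.70). The T-box factor Tbx21 was 7.43 in LSEC-primed, 6.47 in naive, 7.22 in effector and 10.13 in memory cells. Cd274, which encodes PD-L1, was 9.90 in LSEC-primed cells against 9.07 in naive (adjusted p = 0.00942) and 8.62 in effector cells (adjusted p = 0.000206), calls that also ended with median scaling. Lef1 and Cd69 were lower in LSEC-primed than in naive cells, by log2 differences of -1.29 (SE 0.23) and -1.25 (SE 0.21), the latter call ending with median scaling. Tnf differed by 0.09 (adjusted p = 0.931) between LSEC-primed and naive cells, Il2rb by -0.10 (adjusted p = 0.864), Bcl2 by -0.63 (adjusted p = 0.147), Eomes by -0.42 (adjusted p = 0.337) and Ly6c1 by -0.26 (adjusted p = 0.622). The probes of Gzmb, Pdcd1 and Cd8a were not above background on any LSEC-primed, effector or memory array, except Cd8a on 1 LSEC-primed array, so these genes gave no level.

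A total of 85 genes differed at least 2-fold in LSEC-primed cells from all 3 other groups, 78 higher and 7 lower. The members of the endothelial list among the 78 were Robo4, Cdh5, Emcn, Esam and Lyve1. Those of the stellate cell list were Bgn, Dcn, Acta2 and Sparc. Outside these lists, the 78 also held Angpt2 and the collagen genes Col4a1 and Col4a2. RNA of the coculture partner therefore stays open as a source for part of this count, and how large a part was not tested. The higher genes included Igfbp7, Angpt2, Cxcl9, Ubd, Bgn and Serpinh1, a collagen chaperone. The smallest difference of Igfbp7 was 3.41, from effector cells, and Serpinh1, at background on every array of the other groups, was at least 4.1-fold higher. Angpt2, Cxcl9, Ubd and Bgn were above background on 1 of the 3 memory arrays, and their means lay 3.39, 3.19, 3.10 and 2.71 above those of memory cells. Egr3, measured in all groups, had a smallest difference of 2.03. The lower genes included Junb, Il18r1, Cxcr4, a chemokine receptor, Sytl2, Rgs1 and Clk1, with smallest differences from 1.81 for Junb to 1.08 for Clk1. For Junb the call against memory cells (-1.90, SE 0.52, adjusted p = 0.0204) ended with median scaling, with array weights, and without memory sample 3 or 5 or LSEC-primed sample 4 or 7. With the mean of all probes of a gene in place of the brightest probe, 51 genes were counted.

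The reference comparisons gave the range of change within the series. Effector cells differed from naive cells in 4368 genes, 2338 higher and 2030 lower, with 53.5% higher, or 2506 genes and 76.3% higher with median scaling. Mt1 rose by 7.15 (SE 0.48), Aldoc by 5.39 (SE 0.19) and Lag3 by 5.04 (SE 0.47), while Klf2 fell by 5.21 (SE 0.32). The haemoglobin genes Hbb-bs, Hbb-bt and Hba-a1 fell most among called genes with groups that do not overlap. Mgarp was at least 35.3-fold higher, and Aldoc was above background on 1 naive array. Cell cycle genes rose for 40 of 47 and fell for 1 (adjusted p = 1.07e-28, and adjusted p = 0.000994 with an estimated correlation). Glycolysis genes rose for 17 of 20 (adjusted p = 3.07e-17, and adjusted p = 0.0056 with an estimated correlation), as did cholesterol genes for 16 of 17 (adjusted p = 2.02e-18, and adjusted p = 0.000847 with an estimated correlation). Adjusted over the list alone, these counts were the same. Interferon-stimulated genes fell for 18 of 32 and rose for 1, or 19 and 1 adjusted over the list alone (adjusted p = 1.2e-07, and adjusted p = 0.162 with an estimated correlation).

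Memory cells differed from naive cells in 2241 genes, 1099 higher and 1142 lower, 49.0% higher, against 3.34% with median scaling. The count was 1433 with cyclic loess normalisation and 1246 without both dim memory arrays. Memory-associated surface molecules rose for 13 of 19 and fell for 1, the same as adjusted over the list alone (adjusted p = 4.91e-17, and adjusted p = 1.48e-05 with an estimated correlation). The NK cell marker list was also higher in memory cells (camera adjusted p = 4.57e-06), at a mean of 7.821 ± 0.562 against 6.3 ± 0.149 in naive cells. Zeb2 rose by 4.73 (SE 0.17) and Ifng by 3.64 (SE 0.22), above background on 1 and 3 of 5 naive arrays. S1pr5 was at least 23.1-fold, Fcgr2b 19.6-fold and Klrg1 19.2-fold higher. St6gal1, a sialyltransferase, fell by 4.09 (SE 0.23), the tubulin gene Tubb2b by 3.99 (SE 0.18) and Ccr7 fell by 3.49 (SE 0.32), Tubb2b being above background on 1 and Ccr7 on 2 of 3 memory arrays. Nme7, a nucleoside diphosphate kinase, fell by 4.28 (SE 0.23), but its 8 probes ran from -4.28 to 1.45. Memory and effector cells differed in 4294 genes, 1970 higher and 2324 lower, 45.9% higher in memory cells, against 3.63% with median scaling. Ccl5 was higher in memory than in effector cells by 6.86 (SE 0.23) and Ly6c1 by 5.27 (SE 0.23), and the hypoxia-induced prolyl hydroxylase Egln3 was lower by -4.52 (SE 0.27), above background on 2 of 3 memory arrays. The haemoglobin genes Hbb-bs and Hbb-bt ranked next after Ccl5 among the highest, and Mgarp and Aldoc were the lowest.

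The fold changes of LSEC-primed over naive cells were then set beside those of effector and memory cells over the same naive arrays, to ask how much of either programme the LSEC-primed cells carried. Of 870 genes at least 2-fold higher in effector than naive cells, 492 (56.6%) were also called higher in LSEC-primed cells, and of 664 lower genes 374 (56.3%) were also called lower, while 15 were called in opposite directions. Independent lists would share 87.4 and 38.2. Of 328 genes higher in memory cells 142 (43.3%) were called higher in LSEC-primed cells, and of 341 lower genes 198 (58.1%) were called lower, where independent lists would share 32.9 and 19.6, with 29 called in opposite directions. With median scaling, 385 genes were shared with effector cells in place of 866, and 156 with memory cells in place of 340. Simulated unchanged groups against the same naive arrays shared 0 calls in all 100 simulations, but none had any call in the LSEC-primed comparison, so this 0 sets no level for the counts above. With the naive arrays split between the comparisons, the means were 390 and 287 shared genes for effector cells and 116 and 157 for memory cells. Across 23699 features, which are not independent replicates, the correlation was 0.655 with effector cells, against 0.442 for simulated unchanged groups (range -0.239 to 0.832), and 0.413 with memory cells (0.204 with median scaling), against 0.39 (range -0.445 to 0.774). The covariance was 0.159 with effector cells, against a simulated 0.0126, and 0.0741 with memory cells, against 0.0122.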

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

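The tests on coculture RNA, T cell share, memory sample 3, the block by sample number and sex were chosen only after the result was seen, whereas the other splits of the samples were not. The prediction for the correlation between parts of the series was written before, but its cut is that of the block by sample number.

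A single sample stood far from the rest of its group for 16 of 297 sets of values tested, where chance gives 14.9. LSEC-primed sample 14 accounted for 7: Lyz1 at 13.28 (others 8.44 to 8.49), Nusap1 at 10.84 (9.44 to 9.50), Egr2 at 9.60 (9.33 to 9.36), Fos at 7.78 (9.38 to 9.66), the dendritic cell and MHC class II markers at 9.23 (7.49 to 7.66), the macrophage markers at 9.46 (6.69 to 7.06), and probes above background at 30.71% (29% to 29.27%). Effector sample 17 accounted for 6: Clk1 at 9.99 (8.81 to 9.09), Egr3 at 7.78 (8.62 to 8.92), Fos at 6.41 (8.34 to 8.79), Id3 at 6.64 (7.11 to 7.20), Itgae at 6.94 (8.82 to 9.37) and Klf2 at 6.83 (8.00 to 8.44). The others were Cd8a at 6.72 on LSEC-primed sample 7 (6.14 to 6.18), Ppp1r15a at 7.38 on effector sample 10 (7.91 to 8.08) and Ifit3 at 7.29 on naive sample 13 (9.62 to 10.50). Of the 16, 14 lay on the 3 samples with Y-linked signal (LSEC-primed 14, effector 17 and naive 13). No explanation was tested for these.

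Endothelial and stromal genes were high on the LSEC-primed arrays. RNA of the endothelial coculture partner is a candidate source. The endothelial list was higher than in naive cells (camera adjusted p = 0.0189 with an estimated correlation). Its member Egfl7 stood at 8.90 ± 0.37 and Igfbp7, outside the list, at 11.35 ± 0.32. That rise restates the pattern and would also follow from expression by the T cells, so it cannot tell these sources apart. The series description calls the T cells isolated or FACS-sorted, but does not say which samples were sorted. How far this removed endothelial cells or their RNA was not tested. On effector arrays, which had no LSEC coculture, Egfl7 stood at 8.25 ± 0.32 and Igfbp7 at 7.94 ± 0.19, so their expression by the T cells stays open. The endothelial list as a whole was not called between effector and naive cells (camera adjusted p = 0.895), at means of 6.553 ± 0.045 and 6.485 ± 0.067. Stellate cell list means were 5.986 ± 0.036 and 5.982 ± 0.031. Expression of other markers by LSEC-primed T cells alone was not tested. Of the endothelial list's 22 markers, 4 were above background on all naive arrays. A lower share of T cells stays open, as does a change in endothelial content. The endothelial list mean rose from 6.485 ± 0.067 to 7.575 ± 0.229. Of 7 lists of other cells 1 fell by more than its spread, that of erythroid markers, from 7.762 ± 0.598 to 5.994 ± 0.037. Erythroid markers were also low in effector cells (6.054 ± 0.066), so their fall does not speak on the share of T cells. The test looked for a rise of most other cell types and cannot detect a mixture with endothelial cells alone.

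Memory sample 3 carried genes otherwise high on LSEC-primed arrays. Of 49 such genes, chosen as at background on all naive and effector arrays and on the other 2 memory arrays, 22 were above background there. The median share of the 49 was 14.9% of the LSEC-primed level (lower quartile 7.13%, upper 23.5%), so LSEC-primed RNA may have entered this sample. The shares ran from -3.378% for Lyve1 to 61.67% for Fkbp9, and the genes included members of the endothelial and stellate cell lists, such as Cdh5 and Dcn. They cannot tell LSEC-primed RNA from endothelial or stromal RNA of another source. When such genes were chosen without the effector arrays, 33 of 72 were above background on memory sample 3 and 23 of these were higher there than on every effector array, which argues against effector RNA as the source of those 23 and leaves it open for the others (of 18 effector genes 0 were above background, median share 2.25%). Of the 2241 genes called between memory and naive cells, 1846 were called in the same direction without memory sample 3, which argues against it as the source of those 1846. No biological explanation was tested.

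Within groups, the 6 samples numbered above 11 lay lower on average on the first axis of the residuals (mean -0.957, against 0.522 for the other 11). This axis held 29.9% of the within-group variance. The ranges overlapped, at -1.571 to -0.6289 against -1.026 to 2.1, with memory sample 3 at -1.026. None of the 6 was a memory sample, so the split is uneven in every comparison with memory cells. With this split as a block 2932 genes were called between LSEC-primed and naive cells, against 2601 without it. Both groups had samples on each side of the split (naive 12 and 13 and LSEC-primed 14 and 15 above it). A shift alike in both groups could therefore hardly make such calls, so the count does not decide on a batch as their source. Fold changes from the 2 parts correlated at 0.743 across features. The 3 samples with Y-linked signal differed on the residual axis from the other high-numbered ones by -0.279 SD. The limit set for this test cannot be reached with so few samples, so it could not decide on sex. High-numbered samples without Y-linked signal also lay low, at -1.208 to -0.7263, against -1.571 to -0.6289 for those with it. A batch that shifts all groups alike stays open as a source of this axis.

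Other splits of the samples into groups of the same sizes gave as many genes in 1 of 100 splits (the real one included) for LSEC-primed over naive (2601, highest other 785), over effector (2921, 1412) and for effector over naive (4368, 0), in 1 of 35 for LSEC-primed over memory (2554, 837), and in 1 of 56 for memory over naive (2241, 11) and over effector (4294, 4). The same held in 1 of 100 for the 85 particular genes (highest other 0) and for the 866 genes shared with effector cells (highest other 7), and in 2 of 100 for the 340 shared with memory cells. Chance can be excluded for the counts of genes called between groups. For the particular and shared genes the labels of all 17 samples were dealt out anew, which removes every group difference. Those splits therefore show only that the groups differ, and set no level for how many genes would be shared by chance. The other split that reached the 340 shared with memory cells gave 741. That points to a structure of the samples, and what sets that split apart was not tested. For the counts of lists called, chance cannot be excluded in any comparison. The count for LSEC-primed over effector was rarely reached (14, in 2 of 100), but another split gave the same count (highest other 14). That share was not adjusted for the comparisons tested. More splits reached the count for LSEC-primed over naive (10, in 15 of 100, highest 12) and over memory (12, in 4 of 35, highest 16). The same held for effector over naive (9, in 26 of 100, highest 14). It also held for memory over naive (7, in 16 of 56, highest 11) and over effector (11, in 4 of 56, highest 11).

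Single called lists were read by whether under 5% of splits gave a p as small. That limit was not adjusted for the 63 called pairs of a list and a comparison, so meeting it does not by itself exclude chance. The following lists did not meet it. Over naive these were, of 100 splits, inhibitory receptors (10), cell cycle (8), glycolysis (18), fatty acid oxidation (12), immediate-early genes (14) and erythroid markers (10). Over effector, of 100, they were inhibitory receptors (9), fatty acid oxidation (19), oxidative phosphorylation (8), MYC targets (35) and macrophage markers (67). Over memory, of 35, they were trafficking (3), cytokine receptors (6), cell cycle (3), oxidative phosphorylation (2), endothelial (2), B cell (6) and stellate cell markers (4). In the reference comparisons they were, for effector over naive, of 100, the T cell receptor (8), interferon-stimulated genes (17) and macrophage markers (38). For memory over naive, of 56, it was the cell cycle (11), and for memory over effector, of 56, trafficking (4), the T cell receptor (5) and fatty acid oxidation (4).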

How the results depend on the processing

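The alternatives that filter on estimated background, leave out both dim memory arrays or block by sample number were chosen only after the result was seen. Of 662 called pairs of a named gene and a comparison, 382 kept their call under every setting run for single genes (31 to 33 each), and 28 of 63 called pairs of a list and a comparison under the 34 run for lists, while 92 gene pairs lost it without some replicate. Counts of genes called stayed within 1.5 times when 1 replicate was left out. Slide as a block was not run, since no slide is given. Normexp with offset 50 then quantile was identical to the reported values and moved nothing. The causes of the changes below were not tested, except where fewer samples, genes or groups enter by construction.

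With median scaling the genes called were 861 for LSEC-primed over naive, 1276 over effector and 2506 for effector over naive. The percent higher was 31.19 for LSEC-primed over effector, 97.38 over memory, 76.34 for effector over naive, 3.342 for memory over naive and 3.634 for memory over effector. The correlation with memory over naive was 0.2043, genes shared with memory 156 and with effector 385, and lists called 9 for LSEC-primed over effector and 14 for memory over naive. Reversed list medians were 1.254 (T cell receptor) and 0.8054 (unfolded protein response) for LSEC-primed over memory, -1.256 (T cell receptor) and -0.724 (apoptosis) for memory over naive, and -0.8792 (MYC) for memory over effector, where Cd44 also reversed to -1.465. Cyclic loess gave 1221 genes for LSEC-primed over memory, 1433 for memory over naive, a correlation of 0.5758 and, in memory over naive, a cholesterol test whose direction turned (median 0.2797). It ended the calls of inhibitory receptors and fatty acid oxidation over naive, MYC over effector, B cell markers over memory, the T cell receptor for effector over naive and the cell cycle for memory over naive.

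The stricter filter gave 9 lists for LSEC-primed over effector, the mean of probes 51 particular genes, array weights 1658 and only the 2 groups compared 1144 genes for LSEC-primed over memory. The stricter filter also ended the inhibitory receptor and fatty acid calls over naive and over effector, and the costimulation, MYC and unfolded protein response calls over effector. Every probe as a feature, or the mean of probes, ended the inhibitory receptor calls over naive and effector. Every probe as a feature ended that call over memory, and the cytokine receptor call there. The estimated background filter ended the calls of fatty acid oxidation over naive, of inhibitory receptors, fatty acid oxidation, MYC and the unfolded protein response over effector, and of B cell markers over memory. In the reference comparisons it ended the T cell receptor, fatty acid oxidation and macrophage marker calls for effector over naive, the cell cycle for memory over naive, and trafficking and fatty acid oxidation for memory over effector. An estimated correlation gave 4 lists over naive and 6 over effector. A test beyond 1.5-fold, a stricter question, gave 394, 620 and 392 genes for LSEC-primed over naive, effector and memory, 1333 for effector over naive, 352 for memory over naive and 1284 for memory over effector, with 41.13% higher over effector. Without both dim memory arrays, which leaves a lone memory sample assumed to vary like the other groups, 1383 genes were called over memory and 1246 for memory over naive. The sample number block gave 11 lists for memory over naive. On memory sample 5, 15.4% of probes lay above background, which limits what its array can measure.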

Other observations

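No tests are reported here, and the counts were chosen after the data were seen. The probes of Echs1, Kif23, Ndufb8 and Nme7 included probes called in opposite directions in at least 1 comparison. The medians and means of 31 of 186 pairs of a list and a comparison, or the direction of their test, differed in sign, and 0 of these pairs were called. The 2 deposited tables ranked the probes alike within each sample, at a rank correlation of 1.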
